A study of Mus musculus with 19 samples.

How the data were processed

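The analysis started from the files of spot signals that the authors had deposited for each array, as summed spot intensity with its background and summed local background. Per the file headers, these intensity values are the authors' sums over the area of each spot, and the sources describe no normalization of them. The sources name neither the scanner nor the software. They describe 5 µg of total RNA per sample, reverse transcribed together with the added yeast mRNAs from oligo-dT and random primers. The authors also deposited a table of values on a log10 scale with 246 entries per array. Within a tolerance of 0.01 log10, 236 entries equalled the log10 signal of the spot of that name less the mean log10 signal of 21 yeast spots of the array, and 10 entries equalled that of a differently named spot. The 15 spots involved include Fasn, Nr0b2, Gsta3, Thrsp, Abcc6, Gss and C16SR, and names here follow the files of spot signals. The spot named Abcc6 there, with a mean log2 raw signal of 22.42 and rank 2 among the mouse spots, is named C16SR in the authors' table. Which name is right was not settled. Under the name Abcc6 it is 1 of the 11 tested genes of bile acid synthesis and transport. The table leaves out 49 of the mouse spots.

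Background was handled by normexp with an offset of 50, since the median raw mouse signal, 11201, was above 500. Signals were put on the log2 scale, the spots of a probe were averaged, and the 291 mouse probes were scaled by quantile normalization, so yeast spots played no part in the scaling. A probe was tested when its raw signal lay above the mean plus 2 SD of the DMSO spots on at least 4 of the 19 arrays, which held for 180 probes. Of the 291, 93 were above that level on every array and 81 on none. Spot names were matched to current symbols with the RefSeq gene table of GRCm38.p6, 280 of them by gene number, and 20 were renamed.

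The 4 groups were fitted with limma 3.58.1 in R 4.3.3 with 1 shared spread, tests were two-sided, and p values were adjusted by Benjamini-Hochberg over the 180 genes of each comparison, with a threshold of 0.05. The dose trend was fitted on the ranks 0, 1, 2 and 3. A fold for a group at background was computed against the background limit, or against the signal of the group where that was higher, and is written as at least that size. Where some arrays of the dimmer group were above background, the fold is the fitted one, as for Cd36 and Gstt2, with 3 of 6 Control arrays above it, and Gulo, with 2 of 4 D180 and 2 of 5 D1100 arrays above it. A self-test on simulated arrays called 16 of 20 probes changed by 1 log2 and 20 of 20 changed by 2 log2 at D1100, with 2 false calls among 195 unchanged probes. The mean estimates for these probes were 0.77 and 1.57, below the true sizes.

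Gene lists were tested with fry, adjusted over the 13 lists with at least 3 tested genes. Its p concerns genes moving, on balance, 1 way and compares a list with no other genes. With camera, at a preset correlation of 0.01, 2 lists passed at D1100 and 1 at D180. With the correlation estimated, the list of PPARα targets and fatty acid oxidation alone passed at each dose. The 14 lists were PPARα targets and fatty acid oxidation, CAR and PXR targets and xenobiotic metabolism, dioxin receptor targets (1 tested gene, so not tested), sterol synthesis, lipogenesis, bile acid synthesis and transport, nuclear receptors and coregulators, glucose metabolism, lipoproteins and sterol transport, acute phase and inflammation, oxidative stress and NRF2 targets, cell cycle, growth and apoptosis, markers of other cell types, and reference genes. The lists, the comparisons, the scaling and the rule for named genes were chosen before the data were examined. That rule took, at each dose, every called gene up to the 25 with the largest change, 20 fixed genes, and the 2 largest changes of each list at D1100, and the 10 largest called changes for a difference between doses. Replicate numbers were not treated as pairs. Arrays of the same number in different groups had a mean correlation of 0.0442 over 25 pairs, with a range of −0.573 to 0.775. Of 19 arrays, 4 correlated best with their own number. These correlations included Serpina1a and Atp5a1, whose spots lacked signal on some arrays, so they cannot decide whether the numbers stand for pairs.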

Results

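Livers of 19 male C57BL/6J mice were compared after 14 days of daily gavage with corn oil alone or with di-(2-ethylhexyl)-phthalate (DEHP), a plasticizer of polyvinyl chloride. The series asks how DEHP changes the hepatic level of transcripts connected with nuclear receptors. DEHP was given at 3 doses, so the comparisons also show at which dose each gene changed. The Control group held 6 arrays. The groups given 30, 180 and 1100 mg of DEHP per kg body weight per day, called D30, D180 and D1100 here, held 4, 4 and 5 arrays. Each array came from 1 mouse, so the arrays of a group are separate biological replicates. The labels describe 6 treated mice per group, so 5 fewer arrays than mice were deposited.

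Liver RNA labelled with phosphorus-33 had been hybridised to a macroarray of 768 cDNA or control spots. The mouse spots stood for 291 probes, 22 spots held 13 yeast transcripts whose mRNA had been added to each sample, and 451 spots held DMSO alone. The median raw signal of the mouse spots lay between 10440 and 15900 per array in Control, 10700 and 12030 in D30, 8468 and 11080 in D180, and 8783 and 13690 in D1100. The mean signal of the DMSO spots lay between 5231 and 7835, 4679 and 6923, 4141 and 5642, and 4512 and 5100 in the same order. On average 161 mouse probes per array were above background in Control, 167 in D30, 143 in D180 and 144 in D1100. The mean log2 signal of the yeast spots was 19.91 ± 0.32 (SD, n = 6) in Control, 19.83 ± 0.30 (n = 4) in D30, 19.40 ± 0.25 (n = 4) in D180 and 19.50 ± 0.44 (n = 5) in D1100. Of the 291 mouse probes, 180 were tested and 111 were too dim to test. The correlation between arrays of 1 group, across genes, lay between 0.889 and 0.988. The number of arrays limits the precision of each value.

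The lowest dose asks whether the liver responds to 30 mg/kg/day at all. At D30, 3 genes rose and none fell. All 3 are known targets of PPARα, the nuclear receptor that responds to fatty acids and to peroxisome proliferators. Cyp4a14, a fatty acid omega-hydroxylase, rose 6.29-fold (log2 change 2.65 ± 0.24, SE, adjusted p = 1.84e-07). Cyp4a10, a second enzyme of that family, rose 2.43-fold (1.28 ± 0.16, adjusted p = 2.03e-05). Acot1, an acyl-CoA thioesterase of the cytosol, rose 1.79-fold (0.84 ± 0.15, adjusted p = 0.00129). Each of these was higher than the Control mean in 4 of 4 D30 arrays. The calls of Cyp4a14 and Cyp4a10 were made under each of the 5 scalings tried, while that of Acot1 was not made with scaling to the yeast spots or in the authors' value table (adjusted p from 0.00112 to 0.297 over the other scalings). Without adjustment, 18 genes had a limma p under 0.05, where 9 would come by chance. The arrays of D30 and Control did not overlap for 6 genes, where chance gives 1.71 (0.952%).

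Ehhadh, the peroxisomal bifunctional enzyme, did not pass the test at D30 (log2 change 0.45, adjusted p = 0.475, and 0.18 without D30 replicate 3). Without Control replicate 3, 1 gene was called lower at this dose. Of the 13 gene lists tested, 1 rose at D30. The list of PPARα targets and fatty acid oxidation, with 27 tested genes, rose with a fry adjusted p of 0.000368 (adjusted p = 0.0189 with an estimated correlation). Of its genes 3 rose, none fell and 24 did not pass, 23 point estimates were above 0, and 3 rose when adjusted over the list alone. This call was not made with scaling to the yeast spots or in the authors' table (adjusted p from 0.000828 to 0.842 over the other scalings). The other 12 lists did not pass, with an adjusted p between 0.196 and 0.993. One of these, bile acid synthesis and transport, was called lower with median scaling alone (adjusted p from 0.018 to 0.842 over the other scalings). Leaving out Control replicate 6 called the list of cell cycle, growth and apoptosis higher (adjusted p = 0.0213). Within glucose metabolism, 2 genes were lower when adjusted over the list alone, Pck1 and G6pc. Both take part in gluconeogenesis and were named after their values were seen. For both, Control replicates 4 to 6 lay above Control replicates 1 to 3, so the size of these falls depends on the Control arrays used. G6pc stood at 14.841 to 15.206 in Control replicates 1 to 3, 15.967 to 16.316 in Control replicates 4 to 6 and 14.143 to 15.105 at D30. Pck1 stood at 17.602 to 17.794, 18.278 to 18.422 and 17.094 to 17.602 in the same order. The list of CAR and PXR targets and that of reference genes had a median below 0 at D30 (log2 −0.01 and −0.13) beside a test direction above 0.

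The middle dose asks how the response widens. At D180, 12 genes rose and 13 fell. The rises were led by genes of fatty acid oxidation and uptake. The falls included genes of lipoproteins, glucose metabolism and other functions of the liver cell. Without adjustment, 46 genes had a limma p under 0.05. The arrays of D180 and Control did not overlap for 23 genes, where chance gives 1.71.

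Among the rises at D180, Cyp4a14 was 20.6-fold higher (log2 change 4.37 ± 0.24, SE, adjusted p = 2.95e-11) and Cyp4a10 was 7.32-fold higher (2.87 ± 0.16, adjusted p = 2.95e-11). Acot1 rose 3.82-fold (1.93 ± 0.15, adjusted p = 4.96e-09), Ehhadh 3.36-fold (1.75 ± 0.21, adjusted p = 4.08e-06) and Cd36, a fatty acid transporter, 2.63-fold (1.39 ± 0.18, adjusted p = 1.03e-05). The 12 genes that rose were each higher in 4 of 4 arrays. Pex11a, which takes part in the division of peroxisomes, rose 1.88-fold (0.91 ± 0.20, adjusted p = 0.00512), and Fabp1, the fatty acid-binding protein of the liver, 1.87-fold (0.90 ± 0.29, adjusted p = 0.0428). Cyp4a12b, another omega-hydroxylase, rose 1.85-fold (adjusted p = 0.0248). The other rises were Eci2 and Eci1, enoyl-CoA isomerases, Gstt2, a glutathione transferase, and Hsd17b4, a peroxisomal enzyme, with log2 changes of 0.50 to 0.55 (adjusted p from 0.0126 to 0.0317).

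Each of the 13 genes that fell at D180 was lower in 4 of 4 arrays. The largest fall was that of Apoa4, an apolipoprotein of triglyceride-rich particles, at 2.82-fold lower (log2 change −1.50 ± 0.40, SE, adjusted p = 0.0172). Gulo, which makes the precursor of ascorbate, fell 2.04-fold (−1.03 ± 0.31, adjusted p = 0.0288) and Pck1 2.02-fold (−1.02 ± 0.26, adjusted p = 0.0135). For both, the size of the fall depends on the Control arrays used. Gulo stood at 14.596 to 15.049 in Control replicates 1 to 3, 12.961 to 14.002 in Control replicates 4 to 6 and 12.689 to 13.481 at D180. Pck1 was given by Control replicate above. The other genes that fell had log2 changes of −0.85 to −0.59. They included the transcription factors Cebpa (at least 1.43-fold lower, since D180 was at background) and Atf4, the fatty acid synthase Fasn (at least 1.40-fold lower), the cytochrome Cyp1a1, the apolipoproteins Apoa5 and Apob, Hsd11b1, which regenerates glucocorticoid, the chaperone Clu and the carboxylesterase Ces1c. The spot that carries the name Fasn has another name in the authors' table. Cebpa stood at 13.32 to 13.765 in Control replicates 1 to 3, but at 12.455 to 12.646 in Control replicates 4 to 6. At D180 it stood at 11.494 to 12.631, so its fall rests largely on the first 3 Control arrays.

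The split of the D180 calls moved with the scaling. There were 12 higher and 9 lower genes with median scaling, 18 and 0 with yeast scaling, 17 and 9 with cyclic loess, and 15 and 0 in the authors' table, which is itself scaled to the yeast spots. Under yeast scaling the median change over all genes was 0.26, against −0.07 with quantile scaling, so the falls stand relative to the other mouse genes. All 13 kept their sign in every scaling with a value for the gene, none was called in each of them, and 7 of the 12 higher calls were made in each. The 7 were Cyp4a14, Cyp4a10, Acot1, Ehhadh, Cd36, Cyp4a12b and Eci1. One array, D180 replicate 1, weighed on the count: without it 9 genes were called in place of 25 (7 higher and 2 lower), and the 16 lost had an adjusted p from 0.0529 to 0.162. Without Control replicate 1, 10 genes were higher and 8 lower. Leaving out D180 replicate 2, 3 or 4 ended 5, 8 and 4 calls, leaving out Control replicates 1 to 6 ended 6, 3, 3, 2, 2 and 2, and leaving out D1100 replicate 1 ended 1 (adjusted p from 0.0505 to 0.1055). The 9 that stayed in each case were Cyp4a14, Cyp4a10, Acot1, Ehhadh, Cd36, Pex11a, Eci2, Apob and Fasn.

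At the level of lists, 5 of 13 changed at D180. PPARα targets and fatty acid oxidation rose (fry adjusted p = 3.02e-08; adjusted p = 0.000276 with an estimated correlation), with 10 of 27 genes higher, none lower, and 13 higher when adjusted over the list alone. This call was made in every scaling (adjusted p from 1.52e-08 to 0.00968 over the others). Glucose metabolism fell (adjusted p = 0.00387; adjusted p = 0.353 with an estimated correlation), with 2 of 5 genes lower and 3 lower when adjusted over the list alone. Bile acid synthesis and transport fell as a list (adjusted p = 0.00743; adjusted p = 0.353 with an estimated correlation) without a called gene among its 11. Nuclear receptors and their coregulators fell (adjusted p = 0.0102; adjusted p = 0.67 with an estimated correlation), with none of 13 genes called. The 3 reference genes fell as a list (adjusted p = 0.0454; adjusted p = 0.67 with an estimated correlation), with none called. The nuclear receptor list was not called with median scaling (adjusted p = 0.0699), nor the reference list with median scaling or cyclic loess (adjusted p = 0.0938 and 0.101). None of the 4 lower lists was called with yeast scaling or in the authors' table (adjusted p from 0.554 to 0.991), where the medians of the bile acid, receptor and reference lists lay on the other side of 0 in at least 1 of these settings.

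Single arrays also decided some list calls at D180, with 3 lists called in place of 5 without Control replicate 4, D30 replicate 1 or D180 replicate 1. The nuclear receptor list was lost without Control replicate 3, Control replicate 4, D30 replicate 1 or D180 replicate 1 (adjusted p up to 0.085), and the reference list in 10 of 19 cases (adjusted p up to 0.191). Those 10 were Control replicates 2, 3, 4 and 5, D30 replicates 1 and 4, D180 replicates 1, 2 and 4 and D1100 replicate 2. The 8 other lists did not pass, with an adjusted p from 0.0867 to 0.881. Among them, lipoproteins (3 genes lower) passed without Control replicate 6 (adjusted p = 0.0454), cell cycle, growth and apoptosis without the same array (adjusted p = 0.0147), oxidative stress without Control replicate 3 (adjusted p = 0.0353), and markers of other cell types without D180 replicate 4 (adjusted p = 0.0469).

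**Figure D1:**
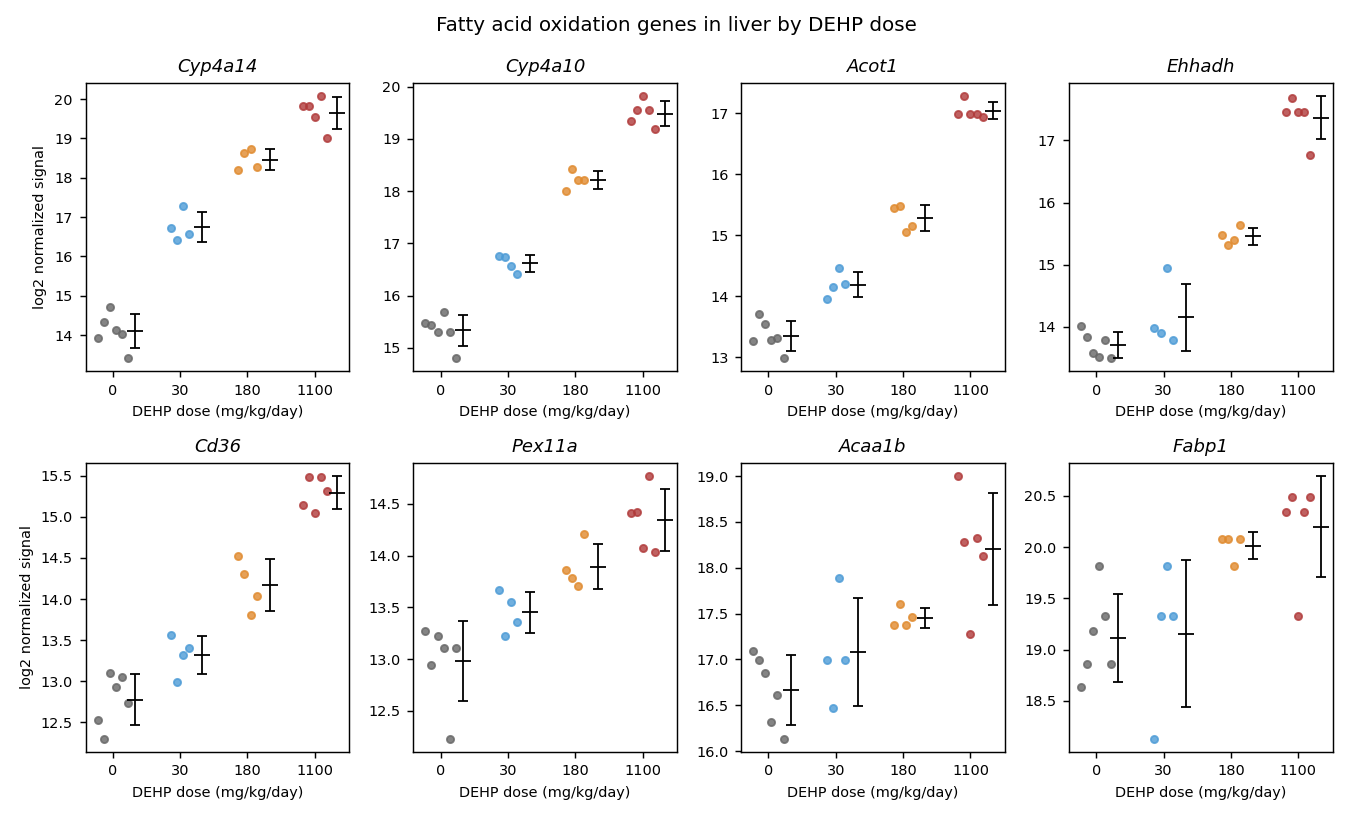
Normalized log2 signal of 8 genes of fatty acid metabolism in each array, by dose of DEHP in mg/kg/day, with the group mean and its SD (n = 6, 4, 4 and 5). The mean of Cyp4a14 was 14.09 in Control, 16.75 at D30, 18.46 at D180 and 19.65 at D1100.

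The highest dose asks which parts of liver metabolism respond beyond fatty acid oxidation. At D1100, 31 genes rose and 51 fell. Fatty acid oxidation rose as at the lower doses. Genes of xenobiotic metabolism changed in both directions. The lists of glucose metabolism, bile acids, lipogenesis and lipoproteins fell, though none of these 4 calls held with an estimated correlation (adjusted p from 0.16 to 0.669). Without adjustment, 97 genes had a limma p under 0.05, and the arrays of D1100 and Control did not overlap for 40 genes, where chance gives 0.779 (0.433%).

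Of the 27 tested PPARα targets and genes of fatty acid oxidation, 18 rose and none fell at D1100, and 20 rose when adjusted over the list alone (fry adjusted p = 2.73e-12; adjusted p = 0.000108 with an estimated correlation). Cyp4a14 was 47.1-fold higher (log2 change 5.56 ± 0.23, SE, adjusted p = 4.01e-14) and Cyp4a10 17.7-fold higher (4.14 ± 0.15, adjusted p = 2.12e-14). Acot1 rose 12.9-fold (3.69 ± 0.14, adjusted p = 2.12e-14), Ehhadh 12.7-fold (3.66 ± 0.20, adjusted p = 5.33e-12) and Cd36 5.73-fold (2.52 ± 0.17, adjusted p = 2.32e-10). Acaa1b, a peroxisomal thiolase, rose 2.90-fold (1.54 ± 0.27, adjusted p = 0.000113), and Pex11a 2.56-fold (1.36 ± 0.18, adjusted p = 6.38e-06). Pdk4, a kinase that slows the oxidation of glucose, was at least 2.34-fold higher, since Control was at background (adjusted p = 0.000673). Fabp1 rose 2.12-fold (adjusted p = 0.00293). These 9 were higher in 5 of 5 arrays. The receptor gene Ppara itself did not pass (−0.18, adjusted p = 0.421).

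Among 18 CAR and PXR targets and genes of xenobiotic metabolism, 5 rose and 5 fell at D1100. Both receptors sense foreign compounds. Cyp2b10, the usual marker of CAR activity, was at least 6.74-fold higher (log2 change 2.80 ± 0.27, SE, adjusted p = 8.3e-08), above background on 5 of 5 D1100 arrays and on none of 6 in Control. Its relative Cyp2b13 rose 3.70-fold (1.89 ± 0.25, adjusted p = 5.63e-06), a fold against a Control group with 1 of 6 arrays above background, and Gstt2 2.48-fold (1.31 ± 0.16, adjusted p = 1.73e-06). Gstp1, a glutathione transferase, fell 2.92-fold (−1.54 ± 0.26, adjusted p = 8.78e-05). These 4 moved the same way in 5 of 5 arrays. The remaining members of these counts, chosen after their values were seen, were Alas1 and Gstm1, which rose, and Ugt1a6b, Gsta3, Ugt2b5 and Abcc2, which fell. The 5 rises were called in every scaling, while of the 5 falls only that of Gstp1 was, and under yeast scaling the other 4 had log2 changes of −0.31 to −0.07 and were not called. The spot named Gsta3 has another name in the authors' table. As a list moving 1 way, this group did not pass (fry adjusted p = 0.0505, adjusted p = 0.669 with an estimated correlation), while the test for changes in either direction did (adjusted p = 2.85e-15). It was called higher with yeast scaling and with cyclic loess (adjusted p from 0.000623 to 0.347 over the other scalings), and without Control replicate 5, D30 replicate 3, D180 replicate 2, D1100 replicate 1 or D1100 replicate 5 (lowest adjusted p = 0.00797). Cyp2c29 (−0.05, adjusted p = 0.846) and Cyp3a11 (0.15, adjusted p = 0.59), other genes induced by CAR or PXR, did not pass, nor did Nr1i3, which encodes CAR (0.03, adjusted p = 0.846). Cyp1a1, the 1 tested target of the dioxin receptor, fell 2.41-fold (−1.27 ± 0.18, adjusted p = 1.61e-05; lower in 5 of 5 arrays).

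All 5 tested genes of glucose metabolism fell at D1100 (fry adjusted p = 3.12e-07; adjusted p = 0.16 with an estimated correlation), and the list was called in every scaling (adjusted p from 5.63e-07 to 0.000534 over the others). G6pc, which releases glucose from the liver, fell 4.02-fold (log2 change −2.01 ± 0.33, SE, adjusted p = 5.71e-05), and Pck1 fell 3.89-fold (−1.96 ± 0.24, adjusted p = 2.47e-06), each in 5 of 5 arrays. G6pc stood at 14.841 to 15.206 in Control replicates 1 to 3, 15.967 to 16.316 in Control replicates 4 to 6 and 12.479 to 14.114 at D1100. Pck1 stood at 17.602 to 17.794, 18.278 to 18.422 and 15.437 to 16.676 in the same order. Both genes were thus below every Control array, but the size of these falls depends on the Control arrays used. The falls also included the glucose transporter Slc2a2 (−1.15) and Fbp1 (−0.42), both named after their values were seen. Fbp1 was called with quantile scaling alone (adjusted p from 0.0602 to 0.69 over the other scalings).

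Bile acid synthesis and transport fell as a list (adjusted p = 1.84e-06; adjusted p = 0.288 with an estimated correlation), with 5 of 11 genes lower. The organic anion transporter Slco1a1 was at least 3.62-fold lower (log2 change −2.36 ± 0.21, SE, adjusted p = 1.78e-08), above background on 6 of 6 Control arrays and on none of 5 at D1100. Cyp7b1, an oxysterol hydroxylase, fell 2.65-fold (−1.41 ± 0.28, adjusted p = 0.00049; lower in 5 of 5 arrays). The others were Abcb11, Slc10a1 and Slc27a5, named after their values were seen and not called under every scaling. The list was not called with yeast scaling or in the authors' table (adjusted p from 2e-08 to 0.126 over the other scalings). Cyp7a1 and the PXR gene Nr1i2 were too dim to test.

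Lipogenesis fell as a list (adjusted p = 0.00869; adjusted p = 0.669 with an estimated correlation), with 1 gene higher and 5 lower of 12. Elovl3, a fatty acid elongase, fell 3.40-fold (log2 change −1.77 ± 0.40, SE, adjusted p = 0.00146; lower in 5 of 5 arrays). D1100 replicate 3 stood at 12.388, against 14.878 to 15.349 on the other D1100 arrays, so the size of this fall depends on that array. With 1 array left out at a time the log2 change was −1.97 to −1.23, and Elovl3 was called in 36 of 36 alternatives. Lpin1, a phosphatidate phosphatase, was at least 1.71-fold lower (−1.74 ± 0.41, adjusted p = 0.00169), with 3 of 6 Control arrays above background. Its level was 12.571 to 12.646 in Control replicates 1 to 3, 13.599 to 14.373 in Control replicates 4 to 6 and 9.825 to 12.489 at D1100. Fasn was at least 1.30-fold lower (−0.73, adjusted p = 0.00169). Lipoproteins and sterol transport also fell (adjusted p = 0.000515; adjusted p = 0.669 with an estimated correlation), with 2 genes higher and 6 lower of 13, and 4 and 7 when adjusted over the list alone. Apoa4 fell 2.85-fold (−1.51 ± 0.38, adjusted p = 0.00293; lower in 4 of 5 arrays) and Apoa5 had a log2 change of −1.05 ± 0.19 (adjusted p = 0.000151). One of the 2 higher genes, Apoe, had a log2 change of 0.89 with quantile scaling, −0.20 with median scaling and 0.15 with yeast scaling, and it was called with quantile scaling alone. Neither list was called with yeast scaling or in the authors' table (adjusted p from 2.53e-05 to 0.87 over the other scalings).

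Nuclear receptors and coregulators fell as a list at D1100 (adjusted p = 0.00128; adjusted p = 0.669 with an estimated correlation) by a median log2 of −0.12, which was also the median over all 180 genes. Under yeast scaling the median of the list was 0.07 and it was not called, as in the authors' table (adjusted p from 0.00236 to 0.87 over the other scalings). Of its 13 genes 3 fell. Nr0b2, a receptor without a DNA-binding domain, had a log2 change of −0.65 (adjusted p = 0.0201), which did not pass without D1100 replicate 2 (−0.50, adjusted p = 0.0707), and its spot has another name in the authors' table. Rarb, a retinoic acid receptor, had one of −0.63 (adjusted p = 0.00189), and Nr1h3, the receptor for oxysterols, was the third, named after its values were seen. Oxidative stress and NRF2 targets fell as a list (adjusted p = 0.039; adjusted p = 0.669 with an estimated correlation) with none of 5 genes called. This call was lost without Control replicate 2, 5 or 6 or D1100 replicate 1, 2 or 3 (adjusted p up to 0.125), and also under yeast scaling, where the median was 0.09, with cyclic loess and in the authors' table (adjusted p from 0.00409 to 0.93 over the other scalings). Markers of other cell types rose (adjusted p = 0.00114; adjusted p = 0.605 with an estimated correlation). The 3 tested genes of that list were all fatty acid-binding proteins, of which Fabp4 rose 2.49-fold (1.32 ± 0.35, adjusted p = 0.00408) against a Control group with 1 of 6 arrays above background, and 2 rose when adjusted over the list alone. The list was not called in the authors' table (adjusted p from 0.000588 to 0.379 over the other scalings).

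The 4 other lists besides CAR and PXR targets did not pass at D1100. Sterol synthesis had an adjusted p of 0.296, acute phase and inflammation one of 0.432, cell cycle, growth and apoptosis one of 0.204 and reference genes one of 0.0505, with none of 6, 3, 4 and 3 genes called. The acute phase list holds Serpina1a, whose spot had no signal on 4 of the 19 arrays, so the result of the list depends on this lack of signal. Without these 4 arrays, an alternative chosen after seeing the data, the list was called lower (adjusted p = 0.000589) and sterol synthesis higher (adjusted p = 0.0292). Without Control replicate 6 the cell cycle list was called higher (adjusted p = 0.0111). The reference list was called lower without Control replicate 1, D30 replicate 2 or 3, D180 replicate 2 or 3 or D1100 replicate 5 (lowest adjusted p = 0.016). The reference genes Actb (−0.10, adjusted p = 0.703) and Rplp0 (−0.22, adjusted p = 0.234) did not pass on their own. Outside the lists, the secreted protease inhibitor Serpina3k fell 2.94-fold (log2 change −1.56 ± 0.13, SE, adjusted p = 8.64e-09) and the complement protein C9 3.02-fold (−1.59 ± 0.23, adjusted p = 1.69e-05). Gulo fell 2.61-fold (−1.38 ± 0.29, adjusted p = 0.000673), Hsd11b1 2.47-fold (−1.31 ± 0.18, adjusted p = 6.38e-06) and Cbs, of homocysteine metabolism, 2.47-fold (−1.30 ± 0.28, adjusted p = 0.000986). These 5 were lower than the Control mean in 5 of 5 arrays. For Gulo, Control replicate 6 stood at 12.961, within the 12.248 to 13.334 of the D1100 arrays.

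The number of lower genes at D1100 depended on the scaling. There were 24 higher and 59 lower genes with median scaling, 34 and 21 with yeast scaling, 43 and 42 with cyclic loess, and 29 and 22 in the authors' table. Over all genes the median change was −0.12 with quantile scaling, −0.235 with median scaling, 0.12 with yeast scaling, −0.01 with cyclic loess and 0.00 in the authors' table. In every scaling with a value for the gene, 24 of the 31 higher and 20 of the 51 lower calls were made. The 20 included Slco1a1, G6pc, Pck1, Elovl3, Serpina3k and Cyp7b1. Of the genes named for D1100 above, Cbs, Apoa5, Rarb, Nr0b2, Nr1h3, Abcb11, Slc10a1, Slc27a5, Ugt1a6b, Gsta3, Ugt2b5, Abcc2 and Fbp1 were among the 31 lower calls missed by some scaling. In simulated data with 232 tested probes on average, of which 31 rose and none fell, quantile scaling called 17.9 probes higher and 18.5 lower on average (at most 24), against 5.3 with median scaling, 1.6 with cyclic loess and 0.25 (at most 1) with yeast scaling. Yeast scaling called 47.4 probes higher there, with a median log2 over all probes of 0.20. The higher-dose arrays also had fewer probes above background than Control, as given above.

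**Figure D2:**
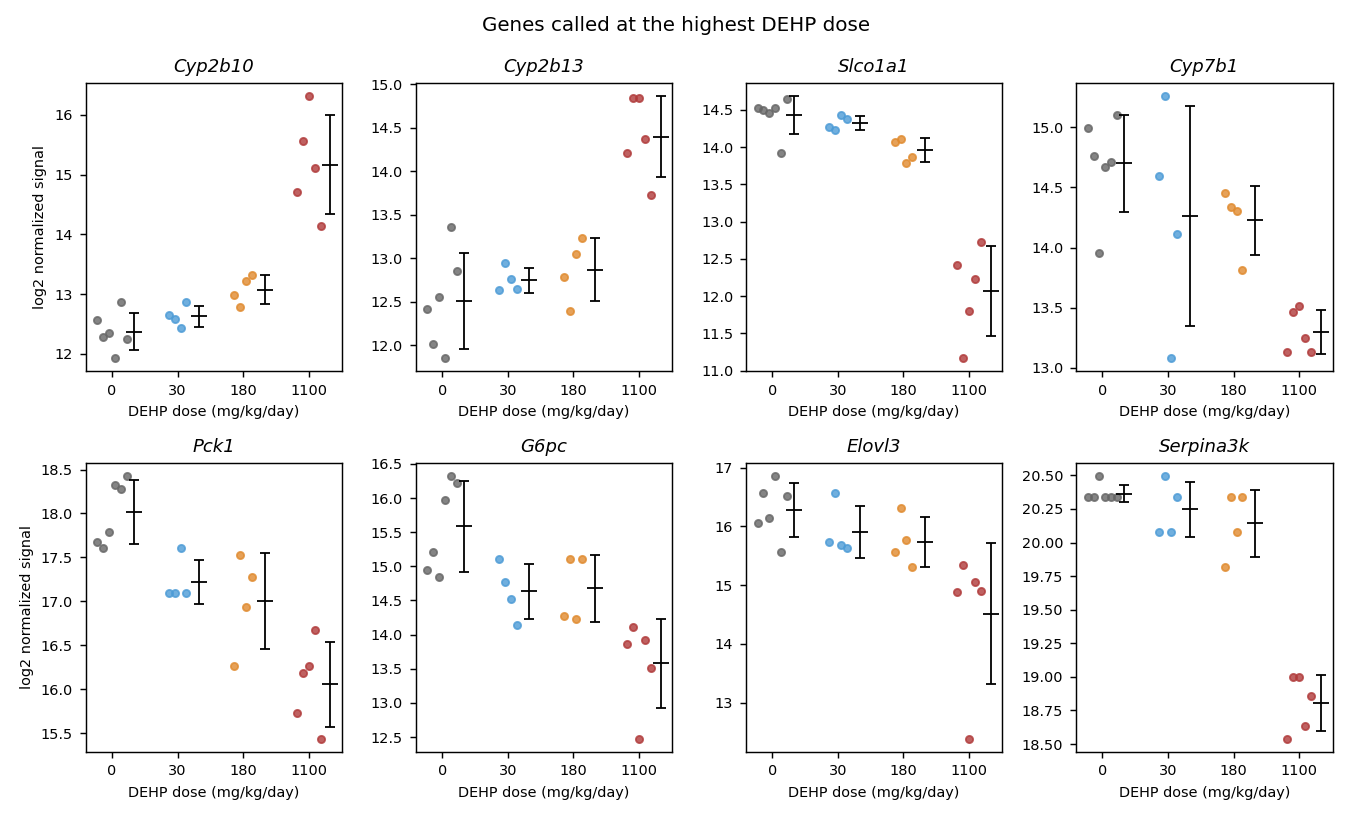
Normalized log2 signal of 8 genes that changed at D1100 in each array, by dose of DEHP in mg/kg/day, with the group mean and its SD (n = 6, 4, 4 and 5). The mean of Cyp2b10 was 12.37 in Control and 15.17 at D1100, and that of Slco1a1 was 14.43 and 12.07.

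Differences between doses show whether a response had levelled off. From D30 to D180, 5 genes were higher and 1 was lower. From D180 to D1100, 9 were higher and 15 lower, and from D30 to D1100, 21 were higher and 36 lower, or 20 and 20 without D30 replicate 2. The list of PPARα targets and fatty acid oxidation rose at each step (fry adjusted p = 0.000319 from D30 to D180 and 2.01e-06 from D180 to D1100, with an estimated correlation 0.00102 and 0.00119). Cyp2b10 and Slco1a1 differed between D180 and D1100, and neither had passed at D180 against Control (log2 0.70 and −0.47).

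Between D30 and D180, Cyp4a14 rose 3.28-fold (log2 change 1.71 ± 0.26, SE, adjusted p = 0.000182), Cyp4a10 3.01-fold (1.59 ± 0.18, adjusted p = 6.09e-06), Ehhadh 2.46-fold (1.30 ± 0.23, adjusted p = 0.000849) and Acot1 2.13-fold (1.09 ± 0.17, adjusted p = 0.000182). Cd36 rose 1.80-fold (0.85 ± 0.20, adjusted p = 0.0137) and Fasn was at least 1.34-fold lower (−0.73 ± 0.20, adjusted p = 0.0464). The call of Cd36 was lost without D30 replicate 2, D180 replicate 1 or D180 replicate 2 (adjusted p = 0.07, 0.079 and 0.0501), and with median scaling (adjusted p from 0.00404 to 0.0713 over the other scalings). The call of Fasn was lost without Control replicate 2, 3, 5 or 6, any 1 of the 4 D30 arrays, D180 replicate 1, 2 or 4 or D1100 replicate 1 (adjusted p from 0.0506 to 0.179), and with median and yeast scaling (adjusted p from 0.044 to 0.515 over the other scalings with a value). The count went from 6 to 10 without D1100 replicate 3, an array of neither group. The counts of higher and lower genes were 4 and 0 with median scaling, 8 and 0 with yeast scaling, 5 and 1 with cyclic loess and 8 and 0 in the authors' table.

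Between D180 and D1100, Cyp2b10 rose 4.27-fold (log2 change 2.09 ± 0.30, SE, adjusted p = 4.11e-05), with 1 of 4 D180 arrays above background, and Ehhadh 3.77-fold (1.91 ± 0.22, adjusted p = 2.5e-06). Slco1a1 was at least 2.61-fold lower (−1.89 ± 0.23, adjusted p = 5.39e-06) and Acot1 rose 3.38-fold (1.76 ± 0.16, adjusted p = 1.42e-07). Cyp2b13 was at least 2.80-fold higher (1.53 ± 0.28, adjusted p = 0.000485). Cyp4a10 rose 2.42-fold (1.27 ± 0.17, adjusted p = 1.54e-05) and Cyp4a14 2.28-fold (1.19 ± 0.25, adjusted p = 0.00196). Serpina3k fell 2.53-fold (−1.34 ± 0.15, adjusted p = 1.66e-06), Ikbkg, a subunit of the kinase that activates NF-kappaB, 2.63-fold (−1.39 ± 0.29, adjusted p = 0.00173), with 2 of 5 D1100 arrays above background, and Mup2, a major urinary protein, 2.37-fold (−1.25 ± 0.20, adjusted p = 0.000156). Quantile scaling gave Mup2 the same top value on the 4 D180 arrays, and its log2 change was −1.43 to −1.84 with the other scalings. There were 9 higher and 21 lower genes with median scaling, 8 and 9 with yeast scaling, 13 and 13 with cyclic loess, and 8 and 9 in the authors' table.

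Between D30 and D1100 the largest changes were those of Ehhadh (9.28-fold higher, adjusted p = 4.54e-10), Cyp4a14 (7.49-fold), Cyp4a10 (7.28-fold), Acot1 (7.19-fold), Cyp2b10 (at least 5.80-fold, with none of 4 D30 arrays above background) and Slco1a1 (at least 3.36-fold lower). Cd36 (3.94-fold), Cyp2b13 (3.14-fold, with 1 of 4 D30 arrays above background), Ucp2, a mitochondrial carrier (2.97-fold), and Pdk4 (at least 2.65-fold) were higher as well. The counts of higher and lower genes were 21 and 37 with median scaling, 24 and 5 with yeast scaling, 27 and 23 with cyclic loess, and 25 and 5 in the authors' table. Along the 4 dose ranks, 32 genes rose and 53 fell. Cyp4a14 rose by a log2 of 1.86 ± 0.10 (SE) per step (adjusted p = 4.72e-13), Cyp4a10 by 1.40 ± 0.05 (adjusted p = 4.47e-16) and Acot1 by 1.21 ± 0.06 (adjusted p = 3.77e-13), while Pck1 fell by 0.62 ± 0.08 per step (adjusted p = 2.48e-06). Yeast scaling gave 49 rising and 22 falling genes, median scaling 25 and 59, cyclic loess 43 and 43, and 37 and 20 were found in the authors' table.

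The doses shared their genes. The 3 genes higher at D30 were also higher at D180 and at D1100. The 12 genes higher and the 13 lower at D180 were called in the same direction at D1100, where independent lists would share 2.07 and 3.68. The shared genes were 12 higher and 9 lower with median scaling, 18 and 0 with yeast scaling, 17 and 9 with cyclic loess, and 14 and 0 in the authors' table. Without D180 replicate 1, 9 genes were shared (7 higher and 2 lower), and without Control replicate 1, 10 higher and 8 lower. The comparisons share the Control arrays, and with the Control arrays split between them, 7.05 higher and 3.8 lower genes were shared on average. Across genes, which are not independent replicates, the correlation of the log2 changes was 0.87 between D180 and D1100, against 0.427 in simulated data without any change, and 0.737 with split Control arrays. For D30 it was 0.474 with D180 and 0.569 with D1100, against 0.411 and 0.418 in simulated data, and it was 0.326 and 0.46 with split Control arrays. All 180 tested genes entered these correlations, also Serpina1a and Atp5a1, whose spots lacked signal on some arrays. Serpina1a stood at 10.602 and 11.217 in D30 replicates 2 and 4, against 22.257 and 21.746 in D30 replicates 1 and 3. The simulated data drew on the same deviations. How far the correlations rest on these spots was not tested.

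**Figure D3:**
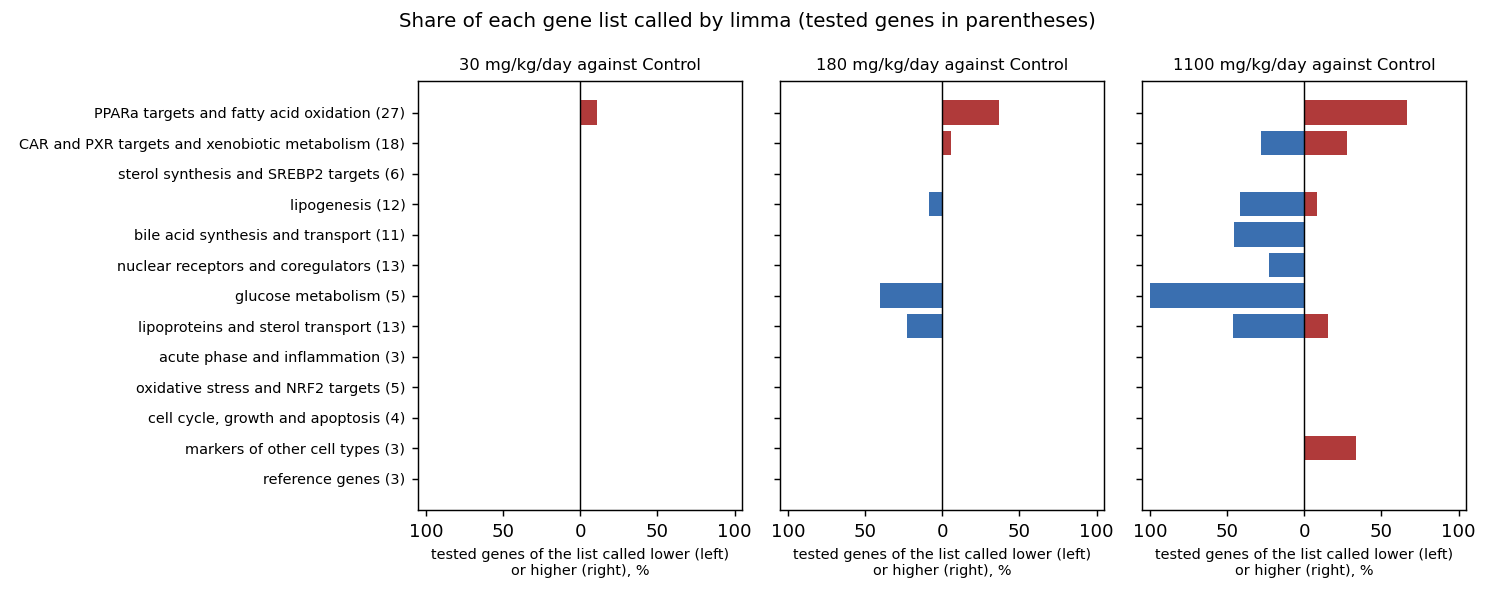
Share of the tested genes of each list, in percent, called higher (right) or lower (left) than Control at D30, D180 and D1100. Of the 27 PPARα targets and genes of fatty acid oxidation, 3, 10 and 18 were higher, and of the 5 genes of glucose metabolism, 0, 2 and 5 were lower.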

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

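The tests that regroup the arrays were planned, and the tests on lower calls at D1100 and on the spots Serpina1a and Atp5a1 were chosen after the results were seen.

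For each named gene and for measures of each array, a sample was singled out when its gap to the nearest other array of its group took up most of the range of the group. Chance does this in about 1 of 20 groups, so 13.6 of the 272 groups, and 28 were found, 8 of them for D1100 replicate 3. The gap as a share of the range was 0.839 for Acot1 in D1100 replicate 2 (log2 level 17.28, others 16.93 to 16.99). Ehhadh had 0.837 in D30 replicate 3 and 0.763 in D1100 replicate 5. Apoa4 had 0.894 in D1100 replicate 3 (15.44, others 12.82 to 13.10), and Elovl3 had 0.901 in D30 replicate 2 and 0.841 in D1100 replicate 3 (12.39, others 14.88 to 15.35). The other genes in D1100 replicate 3 were Fabp1 (0.867), C9 (0.853), Ucp2 (0.821), Gclc (0.838) and Serpina1a (0.916). Pex11a had 0.685 in Control replicate 5, Slco1a1 0.744 in the same array, Ces1c 0.851 in D30 replicate 1, Lpin1 0.714 in D1100 replicate 1 and Ikbkg 0.913 in D30 replicate 3. In D180 replicate 1 the share was 0.907 for Cbs and 0.877 for Fdps. It was 1, which ties between quantile-scaled values produce, in several cases, among them Pck1 in D30 replicate 3, Fabp1 in D180 replicate 3, Hsd17b4 in D180 replicate 1, Serpina3k in Control replicate 3 and Serpina1a in Control replicate 4 (11.79, others 21.75).

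Among the measures of whole arrays, D180 replicate 4 had 113 probes above background against 150 to 156 in its group (share 0.861). Its background limit was 14020, against 8247 to 10320 on the other D180 arrays. Its median mouse signal, 9988, lay within the 8468 to 11080 of the group, so the low count goes with a higher limit rather than with dimmer mouse spots. The mean correlation with the other arrays of the group was low in Control replicate 4 (0.910 against 0.950 to 0.961, share 0.783), in D180 replicate 4 (share 0.893) and in D1100 replicate 3 (0.892 against 0.952 to 0.958, share 0.909). These correlations include the spots Serpina1a and Atp5a1. Control replicate 4 and D1100 replicate 3 were the only arrays of their groups without signal at Serpina1a, and D180 replicate 4 the only one of its group without signal at Atp5a1. The low values therefore do not show that the other probes of these arrays were poor. Spots of DMSO alone should carry no signal, and 8 of them lay above the background limit on most arrays. These 8 were kept in the mean and SD that set the limit, which raised it, so the numbers of probes above background depend on them too. Their mean signal relative to the DMSO mean was 8.43-fold at spot 12K, 2.85 at 8S, 2.94 at 10S, 2.28 at 10T, 2.35 at 2AV, 2.12 at 9N, 2.26 at 12H and 2.06 at 14H.

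Other ways of dividing the same arrays into groups of these sizes were counted, the real one included. Where more than 100 were possible, 100 were used, the others than the real one drawn at random. As many genes were called in 1 of 100 divisions for D30 against Control (3 genes, next highest 2), D180 against Control (25, next 9) and D1100 against Control (82, next 41). The same held for D1100 against D180 (24, next 22), D1100 against D30 (57, next 48) and the dose trend (85, next 42). For D180 against D30 it was 1 of 35 (6, next 0). Chance is thus an unlikely source of these counts, but so few divisions cannot exclude it. The margin was small for D30 against Control and for D1100 against D180. For lists, chance is unlikely in the same sense at D180 (5 lists, 1 of 100, next 4) and at D1100 (8 lists, 1 of 100, next 5). At D30 chance stays a ready source of the 1 list, since 9 of 100 divisions called at least 1 list, as the real one did, and up to 3.

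The 51 lower calls at D1100 may be partly a product of quantile scaling, which pushes other probes down when some rise strongly. For 20 of them this is excluded, since they were called lower in every scaling with a value, the one by yeast spots included, which a rise of mouse probes does not move (median log2 there −1.25). For the other 31 the question stays open. Under yeast scaling 30 of them were lower, with a median log2 of −0.35 against −0.64, and as a set they had a fry p of 0.039, but the set was picked for being lower. That less labelled mouse cDNA per yeast mRNA made them lower was tried and dropped, since it cannot act on quantile-scaled values (median over all probes at D1100 with yeast scaling 0.116).

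A second technical candidate for the lower calls is the smaller number of probes above background on several arrays of D180 and D1100. To test it, lower genes were chosen without the 4 Control and 2 D1100 arrays that have 155 to 161 such probes, which gave 26 genes, 25 of them among the 51. For these it is excluded as the whole source, since between the 6 arrays left out they differed by a median log2 of −1.11, with medians of −1.23 and −1.16 on the D1100 arrays and of −0.0663 to 0.0719 on the Control arrays. For the other 26 lower calls the question stays open, since they were chosen with these arrays included (median −0.675), and 30 of the 51 were among the 93 probes above background on all 19 arrays, where 26.4 would be expected (Fisher's exact p = 0.25). A response of the liver to DEHP stays among the open explanations of the lower calls.

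The spot Serpina1a had no signal on 4 arrays (Control replicate 4, D30 replicates 2 and 4, D1100 replicate 3), at a log2 raw signal of at most 11.99 against at least 20.37 on the others. The spot Atp5a1 had none on these and on Control replicate 6, D30 replicate 1 and D180 replicate 4. All 11 pairs of array and spot lay within 2 SD of the DMSO mean. That test could hardly fail, since a pair counted as without signal when it was at or below the mean plus 2 SD. It therefore does not decide whether cDNA was missing from these spots. The pairs stood between −0.77 and 0.32 SD from the DMSO mean. Weak hybridisation is excluded, since the other probes of the 4 arrays differed by a median log2 of −0.18 within their groups. A response to DEHP is excluded, since 1 Control array lacked the signal at Serpina1a.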

How the results depend on the processing

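The alternatives in the last paragraph were chosen after seeing the data, and the others were planned.

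Over all checks of a called named gene under an alternative, 2980 kept direction and call, 146 kept the direction alone, and none reversed. Of genes not called, 40 became called and 80 changed sign. Kept calls numbered 67 of 86 with yeast scaling, 64 of 82 in the authors' table and 68 of 86 without D180 replicate 1. The causes were not tested unless given here.

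Array weights gave 41 genes for D1100 against D180 and 10 for D180 against D30. In the authors' table there were 51 genes for D1100, 30 for D1100 against D30, 15 for D180, 14 shared by D180 and D1100, and 2, 1 and 0 lists at D1100, D180 and D30. Yeast scaling gave 29 genes for D1100 against D30 and 4, 1 and 0 lists. Testing probes above background on all 19 arrays, which leaves fewer genes, gave 56 trend genes and 3, 3 and 3 lists. Median scaling gave 3 lists at D180 and 2 at D30, the replicate number as a block 2 at D30, camera with a preset correlation 2 at D1100 and 1 at D180, and with an estimated one 1 and 1. Lists whose test changed direction, none called there, are given with their median log2, and were with yeast scaling nuclear receptors (0.0558 at D180, 0.0697 at D1100), reference genes (0.117, D180) and oxidative stress (0.0897, D1100), in the authors' table bile acids (−0.00554), nuclear receptors (0.0166) and reference genes (0.111) at D180, and with the filter on all arrays lipogenesis (0.118, D1100).

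Leaving out 1 array at a time gave 3 to 4 genes at D30, 9 (without D180 replicate 1) to 35 at D180, 73 to 85 at D1100, 4 to 10 for D180 against D30, 19 to 30 for D1100 against D180, 40 to 63 for D1100 against D30 and 75 to 88 for the trend. The overlaps ranged from 3 to 3 for D30 with D180 and with D1100 and from 9 to 34 for D180 with D1100. Lists numbered 1 to 2, 3 to 7 and 7 to 10 at D30, D180 and D1100. Taking the median of the spots of a probe could change nothing, since 4 of the 291 probes had 2 spots and the rest had 1. A batch term was not run because the labels name no batch, and no trend was fitted on 2 groups alone.

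Signal over background limits what can be seen: 111 probes were too dim to test. Chosen after seeing the data, a block for arrays that share spots without signal gave 3, 29 and 80 genes at D30, D180 and D1100. In the same order, leaving out the 4 arrays without Serpina1a gave 3, 30 and 87 (with the call of Acot1 at D30 lost). Leaving out the 15 spots of uncertain name gave 3, 24 and 78, and leaving out Serpina1a and Atp5a1 gave 3, 26 and 81. List calls that changed at D1100 without the 4 arrays were acute phase (called, adjusted p = 0.000589), sterol synthesis (called, 0.0292) and oxidative stress (lost, 0.0652). With the block, oxidative stress was lost (0.0608) and reference genes called (0.0399). Without the 15 spots, CAR and PXR targets (0.0288) and reference genes (0.0462) were called, as without Serpina1a and Atp5a1 (0.0361 and 0.0356). At D180 the reference list was lost with the block (0.0792) and without the 4 arrays (0.0827).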

Other observations

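The test on genes that differ between the sexes was chosen after the results were seen.

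Several of the large changes at D1100 were in genes whose level differs between male and female mouse liver. Of 6 tested genes known as higher in males (Slco1a1, Elovl3, Cyp7b1, Gstp1, Mup2 and Cyp4a12b), 5 fell and 1, Cyp4a12b, rose, with a median log2 of −1.47. Of 4 known as higher in females (Cyp2b13, Cyp2b10, Cyp2c40 and Cd36), 3 rose and none fell, with a median of 2.2. As sets in fry, the male-high genes had an unadjusted p of 8.86e-07 and the female-high genes one of 4.07e-11, and with yeast scaling 0.000629 and 4.27e-09. Apart from Mup2, Cyp4a12b and Cyp2c40, these genes are also on a list tested above. A shift of the male liver toward the female pattern may take part in these changes, but the genes were chosen with their values in view, Cyp2b10 is also a CAR target and Cd36 a PPARα target, and all mice were male, so these explanations cannot be told apart here.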
